A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

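Total RNA from chemostat cultures of Saccharomyces cerevisiae had been hybridised to Affymetrix GeneChip arrays with 1 channel, 1 array per sample. The labels list 12 arrays in 4 groups of 3. The groups combine 2 haploid prototrophic strains of the CEN.PK family with 2 growth regimes. CEN.PK540-3A lacks most of the LEU3 reading frame, replaced by a kanamycin marker between loxP sites, and CEN.PK113-7D is its reference. Growth was limited either by carbon, with ethanol as the carbon source, or by nitrogen, with glucose in excess. Each array was assigned to its group from its title. The titles number the arrays of a group separately, and they were treated as separate samples. The p-values therefore measure differences against the spread between such samples, and 3 per group is the number that limits the precision.

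The deposited values are linear probe set intensity, scaled by the authors so that the mean of each array, without its lowest and highest 2% of probe sets, is the same. That trimmed mean lay between 150.1 and 150.14 on all 12 arrays. The software, the background treatment and the detection calls are not given in the sources used here. Scaling to a common mean leaves differences in the shape of the distribution in place: median intensity ranged from 44.7 to 55.4, and 23.96% to 29.81% of probe sets lay below an intensity of 12. The table held 9335 probe sets. Of these, 6504 were assigned to 1 gene, 328 to several genes and 2503 to none, among them 60 control probe sets. Probe sets without a single gene were left out of the gene tests. The remaining ones covered 5656 genes, 170 of them not protein coding, and for the 315 genes with several probe sets the one with the highest mean log2 value was used.

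Values below 12 were set to 12 and log2 was taken. A gene was tested when its value exceeded 12 on at least 3 of the 12 arrays, which left 5321 genes. One linear model with the 4 group means was fitted in limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 8 residual degrees of freedom shared by all groups. The contrasts were the strain effect (deletion minus reference) under each limitation, their difference (the interaction, nitrogen minus carbon), their average, and the limitation effect (nitrogen-limited glucose minus carbon-limited ethanol) within each strain. Tests were two-sided. Benjamini-Hochberg adjustment ran over the tested genes within a contrast, and a gene passed at an adjusted p under 0.05. Errors of log2 changes are standard errors from the model. Where all arrays of a group lay below 12, the change is a lower bound and is written as "at least". Where only some arrays of the lower group lay below 12, the floor makes the printed change smaller. The limiting nutrient and the carbon source change together in these cultures, so their effects are not separated.

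Gene lists and the choice of genes to name were fixed before the data were examined, as were the model, the contrasts, the floor and the filter. There were 25 lists: classical Leu3 targets (LEU1, LEU2, LEU4, ILV2, ILV5 and GDH1), branched-chain amino acid enzymes, chromosomal neighbours of LEU3, other amino acid biosynthesis, sulfate assimilation and methionine, nitrogen catabolite repression, the Ehrlich pathway, purine and one-carbon synthesis, gluconeogenesis and C2 metabolism, the TCA cycle, the respiratory chain and ATP synthase, peroxisomal beta-oxidation, glycolysis and fermentation, hexose transporters and sensors, ribosome biogenesis, trehalose and glycogen, general stress, phosphate starvation, the retrograde response, a-cell specific genes, alpha-cell specific genes, the pheromone response, meiosis and sporulation, ribosomal proteins and the mitochondrial ribosome. They came from textbook knowledge and not from these arrays. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry asks whether its members move one way on balance. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

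Genes are named by a fixed rule. It takes LEU3 and its neighbours, and every classical target and branched-chain enzyme together with OAC1. It takes the 10 largest increases and 10 largest decreases without overlap between arrays in each strain effect and in the limitation effect of the reference strain, and the 5 largest each way in the other contrasts. It also takes up to 4 members of each list with the largest change past the threshold. Neighbours of LEU3 were read from the RefSeq annotation of the yeast genome. No coordinates were needed, and no read mapping was possible from intensities.

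Control probe sets were checked on every array: the ratio of the 3' to the 5' probe set of actin and of SPT15, which rises when labelled transcripts are shorter, and the signal of bacterial transcripts that some laboratories add to RNA. The model was tested on simulated data in which 200 genes were changed. With 2-fold changes it recovered 87% under nitrogen limitation, 94% under carbon limitation and 64% for the interaction, and with 4-fold changes at least 97% in those contrasts. In these simulated data false calls made up 2.6% to 7.1% of calls over all 6 contrasts. The share of false calls in the measured data was not estimated. There the median SD was 0.245 in the carbon-limited reference and 0.145 in the deletion groups, whereas the model shares its spread over all groups.

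Alternatives set beforehand were no floor, a floor of 50, quantile normalization, centring of each array on the median of the tested genes, no filter, a mean intensity of at least 50, a further requirement of 2-fold change, a variance trend with robust estimation, a fit to only the groups compared, the replicate number as a term, the mean of a gene's probe sets, and the omission of each array in turn. After the control probe sets had been seen, 3 more were added: the log2 actin ratio as a term, the omission of reference carbon-limited arrays 2 and 3, and the omission of reference nitrogen-limited arrays 2 and 3. Each omission leaves 1 reference array in its group, and the spread then comes from the other groups. The actin ratios of the strains do not overlap, so that term also widens the errors of strain effects. A call lost in these 3 settings therefore does not by itself show a smaller effect. Figures were drawn with matplotlib 3.10.9, and tables were prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15. Estimated correlations used statmod 1.5.0.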

Results

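Transcript levels were measured in chemostat cultures of a leu3 deletion strain and of its reference strain, each under 2 nutrient limitations. Leu3 is the transcription factor that controls leucine and branched-chain amino acid synthesis in yeast, and the series carries the title leu3p dependent transcription. There were 12 arrays, 3 for each of the 4 combinations. All cultures grew at a dilution rate of 0.10 per h, pH 5.0 and 30 °C. Carbon-limited cultures received 6.0 g/l ethanol and 5.0 g/l ammonium sulfate. Nitrogen-limited cultures received 1.0 g/l ammonium sulfate and glucose at 59 g/l for the reference and 53 g/l for the deletion strain, to leave a residual of 17 g/l. Spearman correlations between arrays of a group were taken across all probe sets, controls among them. They ranged from 0.984 to 0.992 in the nitrogen-limited deletion cultures and from 0.959 to 0.973 in the carbon-limited reference cultures. Between groups they ranged from 0.906 to 0.972. The median SD of log2 values was 0.15 in both deletion groups, 0.18 in the nitrogen-limited reference and 0.25 in the carbon-limited reference.

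The 3'/5' ratio of actin differed between the strains. It lay between 1.54 and 1.91 on the 6 deletion arrays, at 2.45, 2.55 and 3.29 on the nitrogen-limited reference arrays, and at 3.31, 9.27 and 13.98 on the carbon-limited reference arrays. For SPT15 the ratio was 3.64, 8.08 and 10.1 on the carbon-limited reference arrays and 2.56 to 4.09 on the other 9. Signal of a bacterial control transcript, ThrX-3, was 3095 and 2748 on nitrogen-limited reference arrays 2 and 3 and at most 1.6 on the other 10 arrays.

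**Figure D1:**
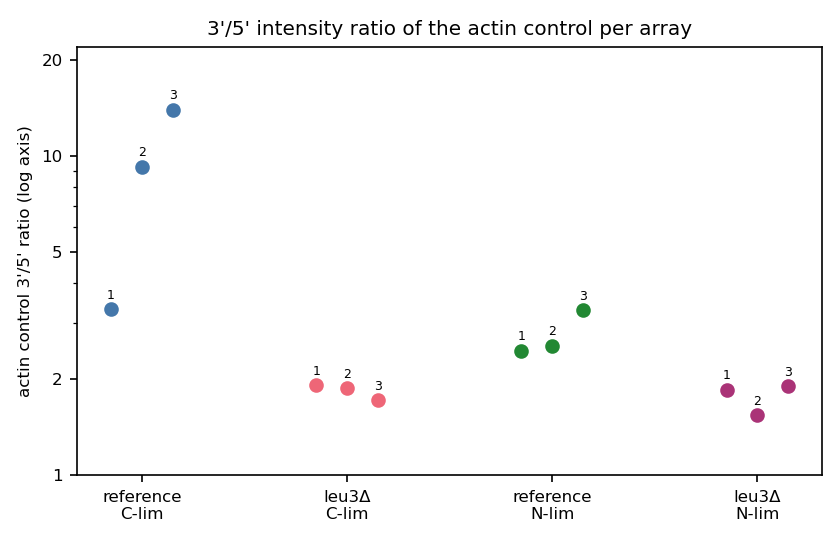
The 3'/5' intensity ratio of the actin control (log axis) for each of the 12 arrays, by group. All 6 deletion arrays lie between 1.54 and 1.91, and carbon-limited reference arrays 2 and 3 stand at 9.27 and 13.98.

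LEU3 (YLR451W) signal lay below the floor on every array of the deletion strain. The positions of its probes relative to the deleted part of the reading frame were not checked, so the values give the signal of those probes alone. Intensity was 102.7 ± 7.1 (SD, n = 3) in the nitrogen-limited reference and 66.3 ± 9.1 in the carbon-limited reference, against 0.3 to 0.6 on all 6 deletion arrays. With the floor of 12, LEU3 was at least 8.54-fold lower under nitrogen limitation and at least 5.49-fold lower under carbon limitation (limma adjusted p = 4.4e-10 and 5.12e-08). Of its neighbours on chromosome XII, HMG2, which encodes an HMG-CoA reductase, fell by 1.06 ± 0.19 log2 under nitrogen limitation (adjusted p = 0.00106) and by 0.95 ± 0.19 under carbon limitation (adjusted p = 0.00245). FMP27 fell by 0.66 ± 0.18 (adjusted p = 0.0147) and by 0.84 ± 0.18 (adjusted p = 0.00334), but its value was 0.01 and -0.02 when its probe sets were averaged. FPR4 (0.00 and -0.21) and SST2 (-0.16 and 0.20) did not pass under nitrogen or carbon limitation, and RIF2 was not tested. Without carbon-limited reference arrays 2 and 3, HMG2 stood at -0.52 and FMP27 at -0.50 under carbon limitation, neither past the threshold. The neighbours as a list did not differ from other genes by camera (adjusted p = 0.193 and 0.104 under nitrogen and carbon limitation), with 2 of 4 members lower in each and 2 not passing, also when adjusted over the list alone. Fry called the list lower under both (adjusted p = 0.00116 and 0.00256).

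The strain effect under nitrogen limitation asks what the loss of Leu3 changes when glucose is in excess and ammonium is scarce. LEU1 and LEU2, which encode isopropylmalate isomerase and isopropylmalate dehydrogenase, fell 3.33-fold and 3.3-fold in the deletion strain. LEU1 changed by -1.74 ± 0.17 log2 (SE, n = 3 per strain, limma adjusted p = 5.88e-06), from an intensity of 633 ± 44.8 (SD) to 190 ± 13.7. LEU2 changed by -1.72 ± 0.14 (adjusted p = 7.19e-07), from 1542 ± 173 to 467 ± 33.3. BAT1, the mitochondrial branched-chain aminotransferase, fell by 1.54 ± 0.16 (adjusted p = 6.17e-06), and the mitochondrial carrier gene OAC1 fell by 0.60 ± 0.17 (adjusted p = 0.0206). On LEU1, LEU2 and BAT1, all 3 deletion arrays were lower than all 3 reference arrays, an arrangement that chance gives one way or the other in 10% of genes.

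Other genes of the pathway were higher in the nitrogen-limited deletion strain. ILV2 and ILV6, the catalytic and regulatory subunits of acetolactate synthase, rose by 0.80 ± 0.14 and 1.06 ± 0.31 (adjusted p = 0.00114 and 0.0215). The isopropylmalate synthase genes LEU4 and LEU9 rose by 0.69 ± 0.14 and 0.99 ± 0.18 (adjusted p = 0.0033 and 0.000987). BAT2, the cytosolic aminotransferase, rose by 1.25 ± 0.15 (adjusted p = 3.6e-05). ILV1 (0.72), ILV3 (0.59) and ILV5 (0.49) also passed, with adjusted p = 0.00304, 0.00905 and 0.0423, and GDH1 did not (-0.04, adjusted p = 0.852). Of the 6 classical targets, 3 were therefore higher, 2 lower and 1 not passing, with the same counts adjusted over the list alone. Their median was 0.22 and their mean -0.25, camera found no difference from other genes (adjusted p = 0.788), and fry called the list lower (adjusted p = 0.00257). All 11 branched-chain enzymes changed, 8 higher and 3 lower (median 0.69, camera adjusted p = 0.0174), with adjusted p = 0.28 with an estimated correlation. Without nitrogen-limited reference arrays 2 and 3, the calls of LEU4, ILV3 and ILV5 ended at about the same size (0.59, 0.60 and 0.53), ILV6 (0.57) and OAC1 (-0.32) ended at a smaller size, and the list did not pass. With the actin ratio as a term the calls of ILV5 (0.36) and ILV6 (0.935) ended. The ILV5 call also ended when any 1 array other than deletion array 2 was left out, and the ILV6 call when deletion array 2 (0.87) or reference array 2 (0.70) was left out.

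**Figure D2:**
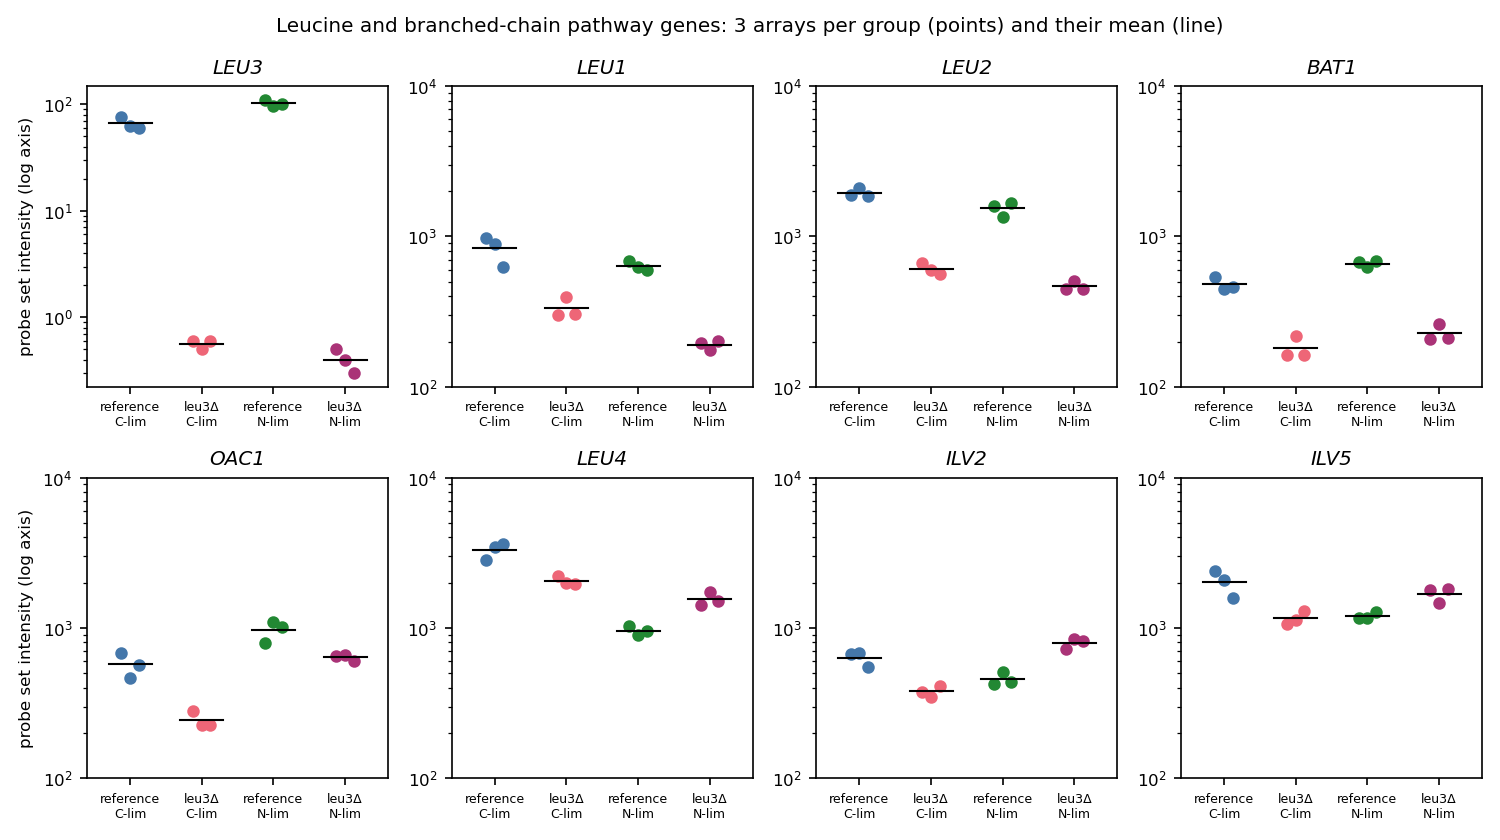
Intensity of LEU3, the classical Leu3 targets other than GDH1, and related genes on each array (points), with group means, on a log axis. LEU1, LEU2 and BAT1 are lower in the deletion strain under both limitations, whereas ILV2 and LEU4 are higher under nitrogen limitation and lower under carbon limitation.

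The largest strain differences under nitrogen limitation lay outside the branched-chain pathway. QDR2, a plasma membrane multidrug transporter, was 38.4-fold higher in the deletion strain (5.26 ± 0.14, adjusted p = 8.09e-13), at 502 ± 12.6 against 13.1 ± 1.0. SNO1 and SNZ1, the divergent gene pair of vitamin B6 synthesis, were 27.86-fold and 11.93-fold higher (4.80 ± 0.22 and 3.58 ± 0.14, adjusted p = 8.42e-10 and 1.16e-10). The other largest increases were ARO5 (3.23), TMT1 (3.10), FMP23 (2.72), YAR068W (2.67), ARO10 (2.61), ARO9 (2.57) and the arginase gene CAR1 (2.40), with adjusted p between 1.85e-09 and 1.15e-06. INO1, which makes inositol phosphate, was 14.81-fold lower (-3.89 ± 0.15, adjusted p = 1.16e-10). GPH1, glycogen phosphorylase, was 8.25-fold lower (-3.05 ± 0.34, adjusted p = 1.73e-05), and MF(ALPHA)1, the gene of the alpha mating factor, was 8.23-fold lower (-3.04 ± 0.19, adjusted p = 3.31e-08) at 37.6 ± 9.3 against 305.5 ± 45.4. The remaining largest decreases were YCL048W-A (-3.18), the hexokinase gene HXK1 (-2.34), the peptide transporter gene PTR2 (-2.18), PDR15 (-2.15), YGP1 (-2.06) and GAC1 (-2.05), with adjusted p between 1.15e-06 and 1.31e-05. For ARO10 on the reference side and GAC1 on the deletion side, 2 of 3 arrays were set to 12, which makes the printed change smaller than the unfloored one.

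Amino acid biosynthesis outside the branched-chain pathway rose as a group. Of 33 measured members, 25 were higher and none lower, also when adjusted over the list alone, with HOM3 at 1.68 ± 0.15, HIS3 at 1.60 ± 0.25, ARO4 at 1.58 ± 0.15 and HIS7 at 1.52 ± 0.15. The median was 0.71 (camera adjusted p = 1.98e-20), and this was the 1 list that held under nitrogen limitation with an estimated correlation (adjusted p = 0.0334). The sulfate and methionine list had 6 members higher, among them MET1 (1.25) and MET16 (0.91), and MUP1 lower (-0.80), out of 20 (7 higher and 1 lower over the list alone; camera adjusted p = 0.00144, 0.295 with an estimated correlation). Genes of the Ehrlich pathway, which degrades amino acids to fusel alcohols, went both ways: ARO10, ARO9, ARO8 and BAT2 rose, PDC6 (-1.82) and PDC5 (-1.14) fell, and 2 of 8 did not pass, with the same counts over the list alone (adjusted p = 0.0168, 0.152 with an estimated correlation). In the nitrogen catabolite repression list 11 of 30 rose and 6 fell (12 and 7 over the list alone), with CAR1 and the allantoin permease gene DAL4 (1.52) higher and the peptide transporter genes PTR2 and OPT2 (-2.02) lower (camera adjusted p = 0.015, 0.282 with an estimated correlation).

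Storage carbohydrate and stress genes were lower. All 10 trehalose and glycogen genes had negative values, and 9 passed over all genes and 10 over the list alone, among them TSL1 (-1.74 ± 0.26), PGM2 (-1.69 ± 0.28) and GLC3 (-1.67 ± 0.26). The median was -1.18 (camera adjusted p = 2.06e-06, 0.28 with an estimated correlation). Of 8 general stress genes 5 were lower, 6 over the list alone, with DDR2 at -1.59, HSP26 at -1.54 and HSP12 at -1.28 (camera adjusted p = 0.00122, 0.282 with an estimated correlation). Some mating genes were lower too. In the pheromone response list PRM1 (-1.42), AGA1 (-1.30), FUS1 (-1.26) and FUS2 (-0.85) fell and 4 did not pass, also over the list alone (camera adjusted p = 0.00508, 0.135 with an estimated correlation). Of 7 a-cell specific genes ASG7 (-0.80), AGA2 (-0.63) and STE6 (-0.54) fell, 5 over the list alone (0.0321, 0.28 with an estimated correlation). Of 3 tested alpha-cell specific genes MF(ALPHA)1 and STE3 were lower, also over the list alone (0.00788, 0.152 with an estimated correlation), and STE3 was below 12 on the deletion arrays and thus at least 1.66-fold lower. Without nitrogen-limited reference arrays 2 and 3 ASG7 (-0.82), AGA2 (-0.60), STE6 (-0.70) and FUS2 (-0.94) did not pass, at about the same size or larger, and AGA2 (-0.41) did not pass with the actin term.

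Of 81 ribosomal protein genes 9 were higher, 1 was lower and 71 did not pass (7 and 1 over the list alone), among them RPS1B at 0.89 and RPS26B at 0.82. Their median was 0.20 (camera adjusted p = 4.71e-08, 0.28 with an estimated correlation). Of 67 mitochondrial ribosome genes 5 were higher, such as MRPS35 at 0.71, and 1 over the list alone (camera adjusted p = 7.17e-06, 0.282 with an estimated correlation). Among 14 peroxisomal beta-oxidation genes 5 were lower, led by POT1 at -1.73, and 6 over the list alone (0.0278, 0.332 with an estimated correlation). NSR1 (1.24) alone rose among 14 ribosome biogenesis genes, and none over the list alone (0.0114, 0.434 with an estimated correlation). ADE8 (0.72) alone rose among 11 purine and one-carbon genes, also over the list alone (0.0227, 0.434 with an estimated correlation). With the actin ratio as a term the last 3 of these lists and the a-cell list no longer passed (0.202, 0.246, 0.246 and 0.106). Without nitrogen-limited reference arrays 2 and 3 the Ehrlich, nitrogen catabolite, a-cell, beta-oxidation and purine lists did not pass. That fit holds 1 nitrogen-limited reference array. Of genes named with these lists, NSR1 stood at 0.74 with the actin term and did not pass. RPS1B and MUP1 stood at 0.97 and -0.50 without those arrays.

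Further lists did not differ from other genes by camera under nitrogen limitation. Glucose transporters split, with HXT2 (1.79) and HXT1 (1.27) higher and HXT6 (-1.10) and HXT7 (-0.86) lower of 9 (adjusted p = 0.702, median -0.27, mean 0.03). In gluconeogenesis and C2 metabolism 7 of 19 fell, such as CAT2 (-1.63), and YAT2 rose (1.03), with 8 and 1 over the list alone (0.24). Among 20 genes of glycolysis and fermentation 5 fell, also over the list alone (0.445), with a median of -0.02 that became 0.12 after centring. SDH1 (-0.61) and ACO1 (-0.53) fell in the TCA cycle list of 16, also over the list alone (0.169). COR1 (0.66) alone changed among 23 respiratory genes, also over the list alone (0.788), with a median of -0.13 that became 0.01 after centring. Of 7 phosphate genes PHM6, PHM8 (-0.73) and VTC3 fell and PHO89 rose, also over the list alone (0.552), with a median of -0.09 that became 0.05 after centring. In the retrograde list DLD3 rose and ACO1 fell of 6, 3 and 1 over the list alone (0.206), and in the meiosis list IME1 rose and SPS4 fell of 5, also over the list alone (0.893, median 0.00, mean -0.17). Without nitrogen-limited reference arrays 2 and 3, SDH1 (-0.81), PHM6 (-0.785), VTC3 (-0.57), PHO89 (0.78) and IME1 (0.55) did not pass, nor did SDH1 (-0.555) and PHO89 (0.38) with the actin term.

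Under nitrogen limitation 1181 of 5321 genes passed, 322 higher and 859 lower in the deletion strain, and 258 of them changed at least 2-fold (100 higher, 158 lower). The median of all genes was -0.11, and centring of the arrays moved it to 0.04 and the split to 538 higher and 485 lower. The number of genes passing without nitrogen-limited reference arrays 2 and 3 is not compared. That fit leaves this reference group without replicates and takes its spread from the other groups.

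**Figure D3:**
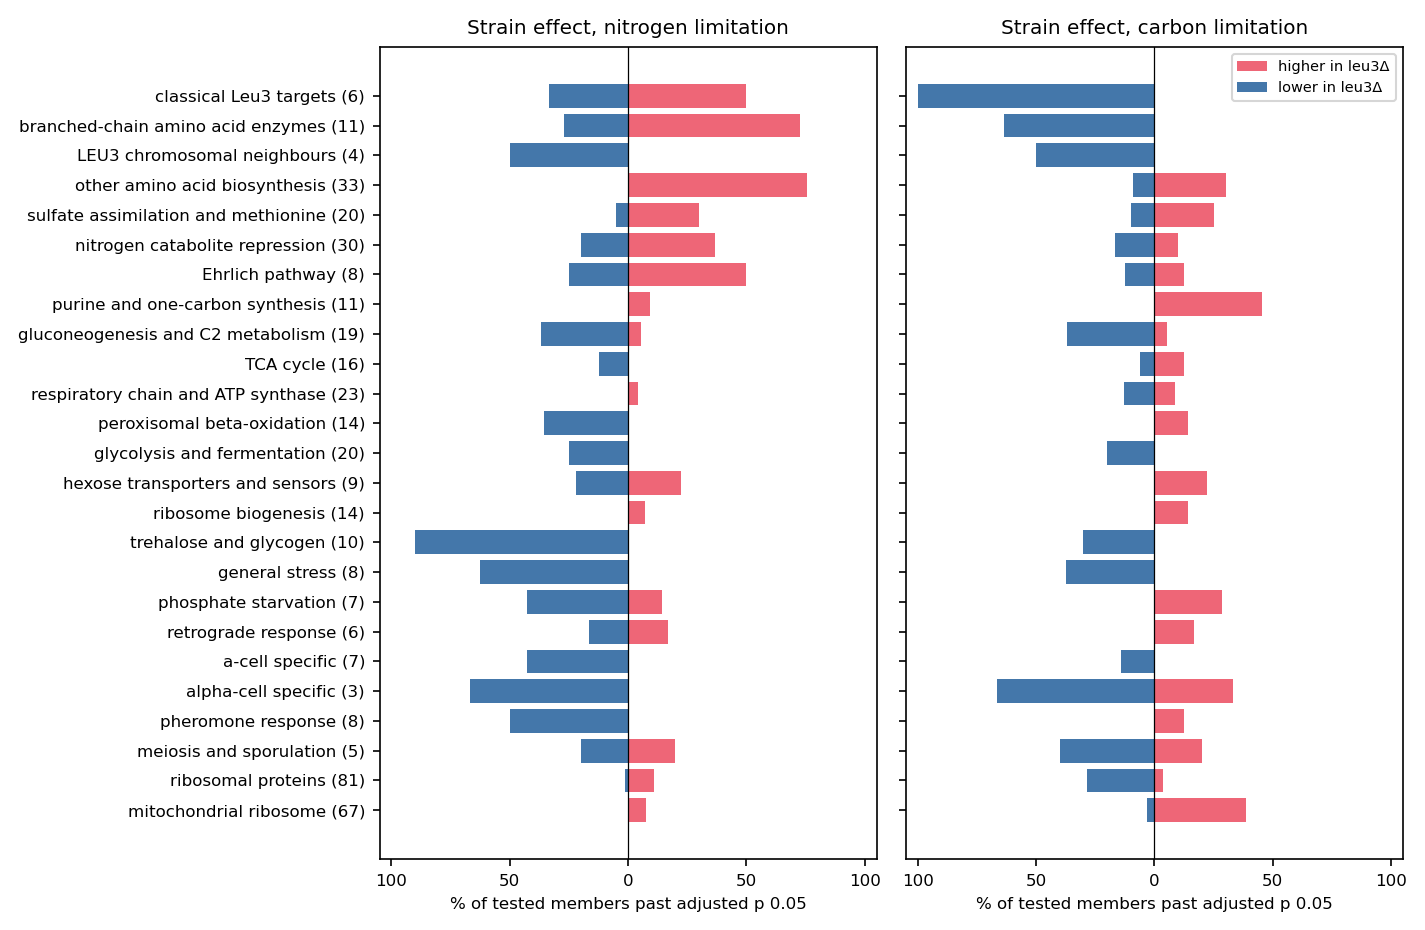
Share of the tested members of each list (number in brackets) that were higher (red) or lower (blue) in the deletion strain, under nitrogen limitation (left) and carbon limitation (right), in percent. All 6 classical targets were lower under carbon limitation, against 2 lower and 3 higher under nitrogen limitation.

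The strain effect under carbon limitation asks the same with ethanol as the limiting carbon source and ammonium in excess. All 6 classical Leu3 targets were lower in the deletion strain. LEU2 changed by -1.68 ± 0.14 log2 (SE, n = 3 per strain, limma adjusted p = 4.64e-06), from 1947 ± 121 (SD) to 609 ± 52.7. LEU1 fell by 1.31 ± 0.17 (adjusted p = 0.000186), ILV5 by 0.78 ± 0.16 (0.00332), ILV2 by 0.74 ± 0.14 (0.00225), LEU4 by 0.67 ± 0.14 (0.00392) and GDH1 by 0.57 ± 0.13 (0.00526). BAT1 and OAC1 fell by 1.42 ± 0.16 and 1.21 ± 0.17 (adjusted p = 4.65e-05 and 0.000268), and ILV3 by 0.58 ± 0.15 (0.00901).

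The classical targets differed from other genes (median -0.76, camera adjusted p = 4.13e-06), with all 6 lower also over the list alone, and this was the 1 list that held under carbon limitation with an estimated correlation (adjusted p = 0.0196). Of 11 branched-chain enzymes 7 fell, also over the list alone, where ILV1 passed upwards (camera adjusted p = 0.000168, 0.101 with an estimated correlation). ILV1 (0.41), LEU9 (-0.38), BAT2 (0.30) and ILV6 (0.00) did not pass over all genes, with adjusted p = 0.0519, 0.123, 0.149 and 1.0. The actin ratio was higher on every reference array than on every deletion array. With that ratio as a term, LEU1, LEU2, BAT1 and OAC1 still passed, whereas LEU4 (-0.36), GDH1 (-0.43), ILV2 (-0.997), ILV3 (-0.49) and ILV5 (-1.20) did not. ILV2 and ILV5 lost the call at a larger size than in the main fit. Without carbon-limited reference arrays 2 and 3, which leaves 1 reference array, LEU4, GDH1 and ILV3 stood at -0.45, -0.48 and -0.54. LEU4 (-0.37) and GDH1 (-0.32) failed after quantile normalization, and ILV3 (-0.47) without deletion array 3.

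BAP2, a branched-chain amino acid permease gene, was 5.6-fold lower in the carbon-limited deletion strain (-2.49 ± 0.18, adjusted p = 1.41e-06), at 14.5 ± 1.0 against 82.4 ± 20.1. The other largest decreases were HPF1 (-2.68 ± 0.48), NAT5 (-1.93), the cyclin gene PCL5 (-1.84), MUB1 (-1.78), MEO1 (-1.74), YOL097W-A (-1.70) and CLG1 (-1.64), with LEU3 and LEU2 among the 10. The largest increase was ATG15, a vacuolar lipase, at 9.67-fold (3.27 ± 0.28, adjusted p = 5.37e-06). PHO84, the high-affinity phosphate transporter, was 6.9-fold higher (2.79 ± 0.22, adjusted p = 4.35e-06), at 89.3 ± 27.1 against 12.3 ± 1.2. For ATG15 and PHO84, 2 of 3 reference arrays were set to 12, which makes the printed change smaller than the unfloored one. The others were PHO4 (2.93 ± 0.40), RPL7B (2.85 ± 0.59), GCN1 (2.54 ± 0.42), ERG12 (2.32 ± 0.37), INO2 (2.26 ± 0.33), YOR302W (2.25 ± 0.40), NIT1 (2.19 ± 0.27) and SFG1 (2.19 ± 0.40), with adjusted p between 0.000115 and 0.00328. These 8 increases no longer passed with the actin ratio as a term. PHO4 (2.03), GCN1 (0.28), ERG12 (0.635), INO2 (0.75) and NIT1 (0.775) shrank, and RPL7B (-0.30), YOR302W (-0.06) and SFG1 (-0.03) turned negative. RPL7B (0.80), GCN1 (1.27), SFG1 (0.89) and HPF1 (-2.265) also failed without carbon-limited reference arrays 2 and 3, and with the actin term HPF1 (-2.61) and YOL097W-A (-1.54) failed at about the same size and MEO1 at -0.70.

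Some genes of translation changed under carbon limitation, on arrays whose actin ratio also differed between the strains. Of 81 ribosomal protein genes 23 fell and 3 rose (28 and 4 over the list alone), with RPL16B at -1.01 ± 0.14 and RPS26A at -0.96 ± 0.21 (median -0.29, camera adjusted p = 5.54e-07, 0.428 with an estimated correlation and 0.264 after quantile normalization). Of 67 mitochondrial ribosome genes 26 rose and 2 fell (28 and 3 over the list alone), with MRP20 at 1.36 ± 0.37, MRPS35 at 1.17 ± 0.16 and MRP8 at -1.19 ± 0.22 (median 0.34, camera adjusted p = 0.000168, 0.551 with an estimated correlation). Neither list turned with the actin term (0.000382 and 6.1e-08), but the named members did not pass with it, MRPS35 at about the same size (1.07), RPL16B at -0.68, and MRP20 (0.58), MRP8 (-0.265) and RPS26A (-0.15) far smaller. In ribosome biogenesis NOP1 (0.96) and RPA135 (0.81) passed of 14, and none over the list alone (0.261), and with the actin term the list was lower (0.0148). Of 11 purine and one-carbon genes 5 were higher, led by ADE2 at 0.90, and 6 over the list alone (0.0133, 0.551 with an estimated correlation), but the actin term turned the direction (0.917). Of 8 general stress genes 3 were lower, also over the list alone, with HSP12 at -1.18 and DDR2 at -0.77 (0.0219, 0.551 with an estimated correlation), and again the actin term turned the direction (0.789). NOP1, RPA135, ADE2, HSP12 and DDR2 stood at -0.70, -0.35, 0.37, -0.36 and -0.11 with the term and at -0.05, 0.03, 0.56, -0.60 and -0.34 without reference arrays 2 and 3, none passing.

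Camera called 2 lists of carbon metabolism lower. In gluconeogenesis and C2 metabolism 7 of 19 fell, such as REG2 (-0.80) and CAT2 (-0.68), and CRC1 rose (0.99), also over the list alone (median -0.31, camera adjusted p = 0.00512, 0.551 with an estimated correlation). In glycolysis and fermentation TDH1, TDH3 (-0.70), FBA1 and ENO1 fell of 20, also over the list alone (0.0418, 0.428 with an estimated correlation). After quantile normalization neither of these lists passed (0.791 for both). None of the 7 named genes passed with the actin term or without reference arrays 2 and 3. TDH1, TDH3, FBA1 and ENO1 stood at 0.20, -0.275, -0.25 and -0.24 with the term and at -0.20, -0.375, -0.335 and -0.38 without these arrays. REG2, CAT2 and CRC1 stood at -0.16, -0.385 and 0.27 with it and at -0.44, -0.435 and 0.52 without them.

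The remaining lists did not differ from other genes by camera under carbon limitation. Other amino acid biosynthesis had 10 of 33 higher, such as HIS7 (1.43) and TRP4 (1.42), and 3 lower, such as ARG3 (-0.85), also over the list alone (adjusted p = 0.302). With the actin term HIS7 (0.95), TRP4 (0.94) and ARG3 (-0.48) did not pass. PHO84 and PHO89 (1.09) were higher of 7 phosphate genes, and 4 over the list alone (0.0979). In trehalose and glycogen TSL1, GPH1 and PGM2 fell of 10, also over the list alone (0.0931). With the actin term they stood at -0.48, 0.53 and 0.01, and without reference arrays 2 and 3 at -0.65, 0.04 and -0.31, none passing. The sulfate list had 5 of 20 higher and 2 lower, also over the list alone (0.582), and nitrogen catabolite repression 3 higher and 5 lower of 30, also over the list alone (0.945, median 0.04 and -0.13 after centring). In the Ehrlich list ARO8 rose and ARO10 fell of 8, also over the list alone (0.435). Among 16 TCA cycle genes ACO1 and KGD2 rose and LPD1 fell, also over the list alone (0.695, median -0.01 and 0.20 after quantile normalization). Respiratory genes had 2 of 23 higher and 3 lower, 2 and 5 over the list alone (0.35, median -0.06 and 0.05 after quantile normalization). POX1 and PIP2 rose of 14 beta-oxidation genes, none over the list alone (0.996, median -0.01, mean 0.05), RGT2 and HXT3 of 9 transporters and sensors, also over the list alone (0.568, median 0.00, mean 0.16), and ACO1 of 6 retrograde genes, also over the list alone (0.942, median 0.02 and -0.15 after centring). MFA2 fell of 7 a-cell genes (0.707, median 0.09, mean -0.07), SAG1 and STE3 fell and MF(ALPHA)1 rose (0.64) in the alpha list (0.51), FUS3 rose of 8 pheromone genes (0.359), and IME1 rose while NDT80 and SPS1 fell of 5 meiosis genes (0.562), each with the same counts over the list alone. FUS3, NDT80 and SPS1 stood at -0.125, 0.29 and -0.13 with the actin term and at 0.31, -0.10 and -0.225 without reference arrays 2 and 3, none passing. Of all genes named in this paragraph only PHO84 and IME1 passed with the actin term, and LPD1 turned positive with it (0.09). Without reference arrays 2 and 3 only PHO84, IME1, HIS7, TRP4 and STE3 passed.

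Under carbon limitation 1494 of 5321 genes passed, 926 higher and 568 lower, and 274 changed at least 2-fold (186 higher, 88 lower). Centring moved the median of all genes from 0.05 to -0.12 and turned the split to 539 higher and 996 lower, and quantile normalization gave 643 and 630. Only 54 genes passed with the actin ratio as a term, and 805 in a fit of these 6 arrays alone.

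The interaction asks whether the strain effect differed between the limitations. It was positive for ILV2 (1.54 ± 0.20 log2, SE, n = 3 per group, limma adjusted p = 0.000274), LEU9 (1.36 ± 0.25, 0.00244), LEU4 (1.36 ± 0.20, 0.000571), ILV5 (1.27 ± 0.23, 0.00244), ILV3 (1.17 ± 0.21, 0.00196) and BAT2 (0.95 ± 0.21, 0.00768). ILV2, LEU4, ILV3 and ILV5 thus rose under nitrogen limitation and fell under carbon limitation, with the difference itself past the threshold. The single calls of these genes ended in some settings, as given above. For LEU1 (-0.43 ± 0.25), LEU2 (-0.04 ± 0.20) and BAT1 (-0.13 ± 0.22) no difference passed (adjusted p = 0.237, 0.902 and 0.717), nor for OAC1 (0.62), GDH1 (0.53), ILV6 (1.06) and ILV1 (0.31), with adjusted p = 0.0851, 0.0573, 0.1 and 0.318. LEU3 itself differed by -0.64 (adjusted p = 0.0303), which reflects the reference values alone, since both deletion groups sat at the floor. It did not pass with the actin term (-0.40), without carbon-limited reference arrays 2 and 3 (-0.42) or without nitrogen-limited reference arrays 2 and 3 (-0.74). BAT2 did not pass without nitrogen-limited reference arrays 2 and 3 (0.74).

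QDR2 (5.26 ± 0.19), SNO1 (4.59 ± 0.31), YAR068W (3.44 ± 0.24), SPG4 (3.34 ± 0.23) and ARO10 (3.12 ± 0.20) had the largest positive differences, with adjusted p between 1.43e-10 and 3.37e-07. The difference of QDR2 equals its effect under nitrogen limitation. A gene set to 12 in both carbon-limited groups would give the same, so the absence of a change there is not shown. MF(ALPHA)1 (-3.68 ± 0.27), INO1 (-3.62 ± 0.21), TLD1 (-2.94 ± 0.32), PHO84 (-2.87 ± 0.32) and YCL048W-A (-2.85 ± 0.38) had the largest negative ones. Among lists, 3 of 6 classical targets were positive, 4 over the list alone (camera adjusted p = 0.000812, 0.0532 with an estimated correlation and 0.0555 after quantile normalization), and 6 of 11 branched-chain enzymes, 7 over the list alone (2.22e-06, 0.0532 with an estimated correlation). Other amino acid genes were positive in 14 of 33, among them ARG8 (1.56) and ARO4 (1.45), with 15 positive and 1 negative over the list alone (5.37e-12, 0.0532 with an estimated correlation). Ribosomal protein genes were positive in 25 of 81, with 35 positive and 1 negative over the list alone (1.41e-18, 0.0577 with an estimated correlation). Pheromone genes FUS1 (-1.80), AGA1 (-1.70), PRM1 and FUS3 were negative, 5 over the list alone (0.00408, 0.0532 with an estimated correlation), but PRM1 (-1.26) and FUS3 (-0.535) did not pass with the actin term. Without carbon-limited reference arrays 2 and 3, which leaves 1 array in that group, PRM1 stood at -1.37. PRM1 and FUS3 also lost their calls with 1 nitrogen-limited reference array, which does not show a smaller difference. The Ehrlich list was positive in 4 of 8 and negative in 2, also over the list alone (0.007, 0.0577 with an estimated correlation). Nitrogen catabolite repression was positive in 10 of 30 and negative in 7, 12 and 7 over the list alone (0.0185, 0.386 with an estimated correlation and 0.113 after quantile normalization). Trehalose and glycogen genes were negative in 4 of 10, 6 over the list alone (0.00699, 0.559 with an estimated correlation). Of 7 phosphate genes PHM6, PHO84 and VTC3 were negative, also over the list alone (0.0365, 0.121 with an estimated correlation and 0.104 with the actin term). VTC3 did not pass with that term (-0.72). It also lost the call without either pair of reference arrays, but with 1 array left in a group this does not show a smaller difference.

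The interaction passed for 976 of 5321 genes, 279 positive and 697 negative, and 443 of them at least 2-fold. Centring moved the median of all genes from -0.20 to 0.11 and the split to 614 positive and 241 negative, and quantile normalization gave 362 and 342. The count was 417 with the actin term.

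**Figure D4:**
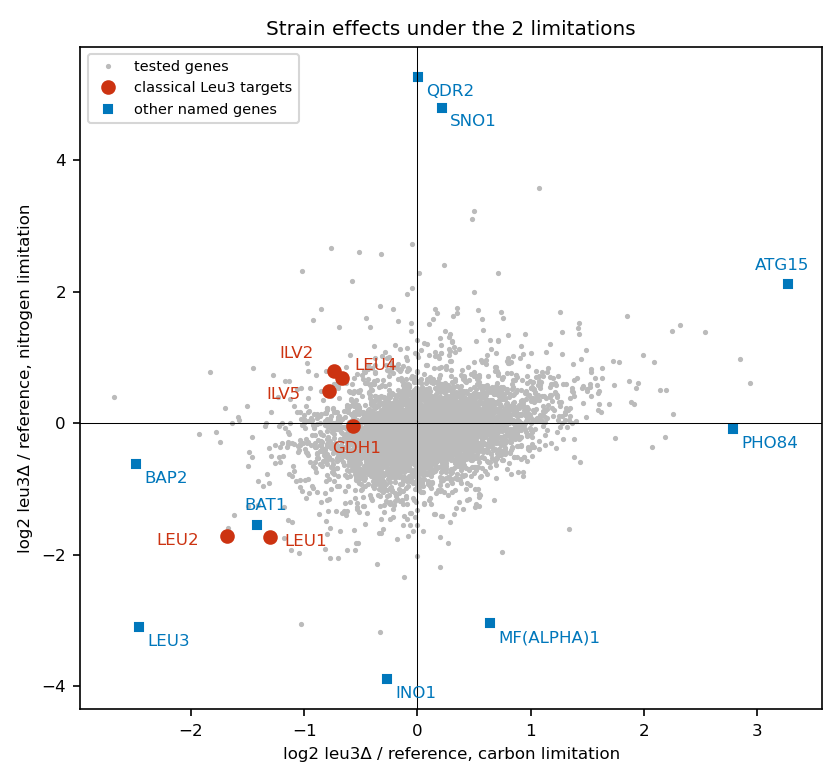
Strain effect (log2, deletion over reference) under carbon limitation (horizontal) and nitrogen limitation (vertical) for the 5321 tested genes, with classical Leu3 targets in red and other named genes in blue. LEU1, LEU2 and BAT1 lie low on both axes, and QDR2, INO1 and MF(ALPHA)1 lie far from 0 on the vertical axis.

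Across the 5321 genes the strain effects under the 2 limitations correlated with Pearson's r = 0.289 and Spearman's rho = 0.289, a description across genes, which are not independent replicates. The r was 0.192 without carbon-limited reference arrays 2 and 3. Genes higher in the deletion strain under both limitations numbered 120, where independent calls would give 56, and genes lower under both numbered 163, where they would give 91.7. Opposite calls numbered 84 against 183.9. Under both limitations every reference array had a higher actin ratio than every deletion array. A difference of the strains shared by both limitations and shorter transcripts on the reference arrays therefore cannot be told apart here. The correlation was not computed with the actin ratio as a term.

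The average weighs both strain effects equally, so a large effect in 1 limitation is enough for a large average. LEU2 (-1.70 ± 0.10, limma adjusted p = 2.32e-08), LEU1 (-1.52 ± 0.12, 9.78e-07) and BAT1 (-1.48 ± 0.11, 3.54e-07) were lower. GDH1 was lower at -0.31, but not with the actin term (-0.22), without carbon-limited reference arrays 2 and 3 (-0.26) or without nitrogen-limited reference arrays 2 and 3 (-0.32). The largest average increases were ATG15 (2.70), QDR2 (2.63), SNO1 (2.51), SNZ1 (2.33) and GCN1 (1.97), and the largest decreases besides LEU3 and LEU2 were INO1 (-2.08), GPH1 (-2.04) and YCL048W-A (-1.76). QDR2, SNO1, INO1 and YCL048W-A passed under nitrogen limitation and not under carbon limitation, with the interactions given above, whereas ATG15, SNZ1, GCN1 and GPH1 passed the same way in both. With the actin term the averages of GCN1 (0.48) and GPH1 (-1.02) did not pass. Under carbon limitation GCN1 and GPH1 were 0.28 and 0.53 with that term and 1.27 and 0.04 without reference arrays 2 and 3, none of them passing. Amino acid genes HIS7 (1.48), TRP4 (1.39) and HIS3 (1.18) were higher, with 21 of 33 in that list up and 3 down, 24 and 3 over the list alone (camera adjusted p = 6.97e-10, 0.212 with an estimated correlation). Trehalose and glycogen genes were lower in 9 of 10, also over the list alone (6.11e-05, 0.378 with an estimated correlation and 0.0751 with the actin term), and stress genes in 7 of 8, also over the list alone (0.000665, 0.378 with an estimated correlation and 0.126 with the actin term). HIS3 did not pass with that term (0.62). Classical Leu3 targets were lower in 3 of 6, also over the list alone (camera adjusted p = 0.0208, 0.212 with an estimated correlation and 0.0643 after quantile normalization). All 3 alpha-cell genes were lower, also over the list alone (0.0115, 0.212 with an estimated correlation), although MF(ALPHA)1 fell under nitrogen limitation and rose under carbon limitation. Mitochondrial ribosome genes were higher in 24 of 67 and lower in 3, 28 and 3 over the list alone (2.59e-07, 0.378 with an estimated correlation). The purine list was higher in 3 of 11, also over the list alone (0.00316, 0.378 with an estimated correlation and 0.71 with the actin term). The sulfate list was higher in 6 of 20 and lower in 1, also over the list alone (0.0367, 0.459 with an estimated correlation and 0.998 with the actin term). Ribosome biogenesis was higher in 3 of 14, 2 over the list alone (0.0203, 0.459 with an estimated correlation), and the actin term turned its direction (0.482). Gluconeogenesis was lower in 9 of 19 and higher in 2, 10 and 2 over the list alone (0.0185, 0.459 with an estimated correlation), and glycolysis lower in 7 of 20 and higher in 1, also over the list alone (0.0493, 0.378 with an estimated correlation). Neither passed after quantile normalization (0.236 and 0.228) or with the actin term (0.0751 for both). On average 1763 genes passed, 765 higher and 998 lower, of which 119 changed at least 2-fold. The count was 220 with the actin ratio as a term.

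The limitation effect in the reference strain compares nitrogen-limited glucose with carbon-limited ethanol cultures. ADH2, the ethanol-oxidising alcohol dehydrogenase, fell by 8.25 ± 0.18 log2 (SE, n = 3 per group, limma adjusted p = 9.39e-15), from an intensity of 6873 ± 1285 (SD) to 22.5 ± 4.1. FBP1, the gluconeogenic fructose bisphosphatase, was at least 175.98-fold lower, and the acetate transporter gene ADY2, RGI2 and the carrier gene SFC1 were at least 181.9-fold, 201.36-fold and 89.04-fold lower. SPG4 (-7.96), the peroxisomal catalase CTA1 (-6.86), ATO3 (-6.19), HXT5 (-5.84) and PDH1 (-5.83) completed the largest decreases. The largest increase was OPT2, at least 118.62-fold higher. The other largest increases were DAL80 (5.90 ± 0.19), DIP5 (5.75 ± 0.19), OPT1 (4.88 ± 0.17), PTR2 (4.22 ± 0.19), the glucose transporter genes HXT3 (5.45), HXT4 (4.75) and HXT1 (4.70), PDC5 (4.26) and EEB1 (3.92).

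By list, all 19 genes of gluconeogenesis and C2 metabolism fell (median -5.02, camera adjusted p = 1.08e-32, 0.0117 with an estimated correlation), as did 15 of 16 TCA cycle genes (1.12e-12, 0.00276), 16 of 23 respiratory genes (2.1e-07, 0.0168) and 13 of 14 beta-oxidation genes, with 1 higher (5.46e-14, 0.0168), each with the same counts over the list alone. Classical Leu3 targets fell in 4 of 6, with LEU4 at -1.77 ± 0.14 and ILV5 at -0.73 ± 0.16, and in all 6 over the list alone (0.00241, 0.0381 with an estimated correlation, but 0.176 after quantile normalization). The retrograde list fell with CIT2 (-1.94), IDH1 and ACO1 of 6, also over the list alone (0.0027, 0.0381 with an estimated correlation, 0.0851 after quantile normalization). ACO1 did not pass without nitrogen-limited reference arrays 2 and 3 (-0.38) or after quantile normalization. Nitrogen catabolite repression genes rose in 22 of 30 and fell in 4, 22 and 5 over the list alone (7.19e-06, 0.0615 with an estimated correlation). The a-cell genes STE2 (2.63), STE6 (2.05), BAR1 (1.89) and AGA2 (1.32) rose, 5 of 7, also over the list alone (0.00429, 0.0665 with an estimated correlation). The alpha factor gene MF(ALPHA)1 rose by 3.82 ± 0.19 (adjusted p = 2.14e-10). Branched-chain enzymes fell in 5 of 11 and rose in 1, 7 and 1 over the list alone (0.00646, 0.109 with an estimated correlation and 0.176 after quantile normalization). Stress genes fell in 4 of 8 and rose in 1, 5 and 1 over the list alone (0.00492, 0.382 with an estimated correlation and 0.145 with the actin term). Mitochondrial ribosome genes fell in 8 of 67 and rose in 3, 7 and 2 over the list alone (0.0079, 0.55 with an estimated correlation and 0.145 with the actin term). Ribosomal protein genes fell in 23 of 81 and rose in 2, also over the list alone (median -0.26, 5.79e-06, 0.307 with an estimated correlation), but quantile normalization turned the median to 0.13.

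In the reference strain 2532 genes passed, 1737 higher and 795 lower under nitrogen limitation, and 772 changed at least 2-fold (479 higher, 293 lower). Centring moved the median of all genes from 0.19 to -0.07 and turned the split to 951 and 1370, and quantile normalization gave 1191 and 984. The count was 1289 with the actin term.

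In the deletion strain, the same contrast gave HXT1 (5.97 ± 0.13), DIP5 (4.91), HXT3 (4.85) and DAL80 (4.71) as largest increases, with OPT2 at least 29.19-fold higher. ADH2 (-7.64 ± 0.18), ADY2 (-6.94) and RGI2 (-6.87) fell, and FBP1 and SFC1 were at least 143.59-fold and 109.88-fold lower. ILV2 (1.07 ± 0.14, adjusted p = 3.21e-05), ILV3 (1.14) and LEU9 (0.94) rose under nitrogen limitation, and LEU1 (-0.80) fell. Other amino acid genes rose in 19 of 33, among them ARG8 (1.29) and ARO7 (1.21), and 21 over the list alone (camera adjusted p = 3.5e-06, 0.124 with an estimated correlation). Nitrogen catabolite repression genes rose in 24 of 30 and fell in 1, also over the list alone (4.36e-13, 0.0122 with an estimated correlation). The gluconeogenic list fell in all 19 (5.81e-31, 0.0122 with an estimated correlation) and the TCA cycle list in all 16 (4.36e-13, 0.00254), also over the list alone. Beta-oxidation genes fell in 13 of 14, also over the list alone (1.06e-14, 0.0122 with an estimated correlation), and respiratory genes in 17 of 23, 19 over the list alone (1.1e-05, 0.033 with an estimated correlation). The other 8 lists that passed camera did not pass with an estimated correlation. Ribosomal protein genes rose in 23 of 81 and fell in 1, 22 and 1 over the list alone (0.00162, 0.404 with an estimated correlation), where 23 fell in the reference strain. Mitochondrial ribosome genes fell in 24 of 67 and rose in 2, 25 and 2 over the list alone (0.00266, 0.404). Trehalose and glycogen genes fell in 6 of 10, 8 over the list alone (0.00162, 0.404), and stress genes in 5 of 8, with 1 higher, also over the list alone (0.00262, 0.33). The a-cell list rose in 6 of 7, with 1 lower over the list alone (0.00406, 0.094), and glycolysis rose in 9 of 20 and fell in 2, also over the list alone (0.0102, 0.173). The retrograde list fell in 4 of 6 and rose in 1, also over the list alone (0.0322, 0.124, and 0.0647 after quantile normalization). The sulfate list rose in 7 of 20 and fell in 2, 8 and 2 over the list alone (0.0335, 0.434). MF(ALPHA)1 did not pass in the deletion strain (0.13 ± 0.19, adjusted p = 0.633), and its interaction was -3.68.

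In the deletion strain 1907 genes passed, 961 higher and 946 lower, of which 603 changed at least 2-fold (260 higher, 343 lower). Across genes the limitation effects of the strains correlated with Pearson's r = 0.773 and Spearman's rho = 0.559. Both strains called 639 genes higher and 465 lower, where independent calls would give 313.7 and 141.3.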

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

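The tests of the 3 patterns weighed below were chosen after the patterns had been seen, and bounds were set before the values of the tests were computed. For the first and second pattern a rule beyond those bounds was used, as stated there. The interaction tests and the splits of the arrays were planned.

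Of the genes named in the report, 84 had a strain effect that differed between the limitations by the interaction test of limma (log2, nitrogen minus carbon), 42 positive and 42 negative. Over all genes tested 976 of 5321 (18.3%) passed. Many genes were named for the size of their effects on these same arrays, so the count of 84 is partly built in. In the branched-chain pathway the named genes were ILV2 (1.54), LEU9 (1.36), LEU4 (1.36), ILV5 (1.27), ILV3 (1.17) and BAT2 (0.95), and in other amino acid synthesis ARG8 (1.56), HOM3 (1.501), ARO4 (1.45) and ARG3 (0.99). The Ehrlich list had ARO10 (3.12), ARO9 (2.89) and ARO8 (0.62), against PDC6 (-1.29) and PDC5 (-1.04). In the nitrogen catabolite repression list CAR1 (2.17) and DAL4 (1.58) were positive and PTR2 (-2.38), OPT2 (-2.02) and DAL80 (-1.19) negative. Vitamin B6 genes were SNO1 (4.59) and SNZ1 (2.50). Trehalose and glycogen genes were GPH1 (-2.02) and GLC3 (-1.35), stress genes HSP26 (-1.42) and DDR2 (-0.81), phosphate genes PHO84 (-2.87), PHM6 (-1.53) and VTC3 (-0.87), and mating genes MF(ALPHA)1 (-3.68), FUS1 (-1.80), AGA1 (-1.70), PRM1 (-1.62), FUS3 (-1.16) and BAR1 (-0.95). Ribosomal protein genes were RPS1B (1.16), RPS26A (1.15), RPL16B (1.14) and RPS26B (1.05). Among hexose transporters and sensors HXT2 (2.12) and HXT1 (1.27) were positive and HXT6 (-1.65), HXT7 (-1.09), RGT2 (-0.97) and HXT3 (-0.60) negative. The others above 0 were QDR2 (5.26), YAR068W (3.44), SPG4 (3.34), HPF1 (3.08), FMP23 (2.77), ARO5 (2.73), TMT1 (2.62), PCL5 (2.62), YOL097W-A (1.93), BAP2 (1.86), NAT5 (1.77), CLG1 (1.65), MUB1 (1.65), MEO1 (1.46), YAT2 (1.34), DLD3 (0.97), RGI2 (0.79), TDH3 (0.77) and CIT2 (0.73), and those below 0 were INO1 (-3.62), TLD1 (-2.94), YCL048W-A (-2.85), SFG1 (-2.40), PHO4 (-2.32), HXK1 (-2.23), INO2 (-2.11), POT1 (-1.93), PDR15 (-1.79), NIT1 (-1.68), OPT1 (-1.59), SPS4 (-1.36), YGP1 (-1.36), EEB1 (-1.32), GAC1 (-1.28), ACO1 (-1.06), KGD2 (-0.87), DIP5 (-0.85) and ADE2 (-0.75). LEU3 (-0.64) differed through the reference arrays alone, since it was below 12 on all deletion arrays. Of the 84, 54 were also run in the tests chosen later, and 15 did not pass with the actin ratio as a term. Among these, PDC5 (-0.999) and RPS1B (1.08) lost the call at about the same size. LEU3 (-0.40), RPS26A (0.59), PRM1 (-1.26), ADE2 (-0.385), TDH3 (0.48) and VTC3 (-0.72) lost it at a smaller size. Some calls were also lost without either pair of reference arrays, but each of these fits leaves 1 array in a group. After quantile normalization 7 of the 54 did not pass, and 9 after centring.

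By camera, 9 lists differed between the limitations: classical Leu3 targets (adjusted p = 0.000812), branched-chain enzymes (2.22e-06), other amino acid biosynthesis (5.37e-12), nitrogen catabolite repression (0.0185), the Ehrlich pathway (0.007) and ribosomal proteins (1.41e-18) with positive values, and trehalose and glycogen (0.00699), phosphate starvation (0.0365) and pheromone response (0.00408) with negative ones. With an estimated correlation none passed, the lowest adjusted p being 0.0532. The bacterial control transcript ThrX-3, which no comparison uses, gave 3094.8 and 2747.7 on nitrogen-limited reference arrays 2 and 3 and at most 1.6 on the other 10.

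The first pattern is the excess of genes higher in the deletion strain under carbon limitation, 926 against 568. After centring, the number higher over the number lower was 0.541, which met the bound set beforehand for scaling as the cause. That bound was set aside by a rule added after the value was seen, because centring shifts all genes of an array alike and so builds in this turn. The balance thus depends on the scaling, and whether scaling is its cause stays open. The median change of the genes called higher was 0.706 against all 3 reference arrays and 0.503, 0.757 and 0.857 against arrays 1, 2 and 3. The ratio for array 1, with the lowest actin ratio of the 3, was 0.713, between the bounds set for and against an effect of shorter transcripts on arrays 2 and 3. Shorter transcripts and a difference of the strains cannot be told apart, because every reference array had a higher actin ratio than every deletion array.

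The second pattern is the 8.23-fold lower MF(ALPHA)1 in the nitrogen-limited deletion strain. Against array 1, which lacks the added control signal, the difference was 0.945 of that against all 3 (-2.87, -2.98 and -3.27 against arrays 1, 2 and 3). This argues against the added control transcripts on arrays 2 and 3 as the cause. Other differences in preparation between the strains were not tested, and array 1 had a higher actin ratio (2.45) than every deletion array. The other alpha-specific genes had a median of -0.41, which met the bound set beforehand against cells of the alpha type in the reference cultures. That bound did not ask for genes above the floor. Only SAG1 was above 12 on all arrays of both groups, STE3 (-0.73) was below 12 in the deletion strain, and MF(ALPHA)2 was below 12 in both. Such cells were therefore left open. Pheromone response genes were also lower in the nitrogen-limited deletion strain (median -0.61, 4 of 8 lower and 4 not passing, camera adjusted p = 0.00508). That list did not pass with an estimated correlation (0.135), and it was not part of the test. An effect of the deletion itself was not tested apart from such cells.

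The third pattern is the lower trehalose and glycogen list in the nitrogen-limited deletion strain. Its median against array 1 was 1.46 times that against all 3 arrays (-1.72, -0.87 and -0.98 against arrays 1, 2 and 3). This argues against the added control transcripts on arrays 2 and 3 as the cause. After centring the list median was -1.04 (-1.038), which met the bound set beforehand against scaling. Centring shifts all genes of an array alike, by far less than the list median, so this bound could hardly fail. The value shows only that such a shift does not account for the decrease. After quantile normalization the list median was -1.08. Other differences in preparation between the strains were not tested, and array 1 had a higher actin ratio (2.45) than every deletion array. The list did not pass with an estimated correlation (camera adjusted p = 0.28). Array 1 alone has no spread of its own, so no test against it is given. An effect of the deletion is a hypothesis found and tested on the same arrays, and the feed glucose also differed between the strains, at 53 and 59 g/l.

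Splits of the arrays were refitted in limma. With 10 splits of 6 arrays there are too few for a share under 0.05. The real counts were 1181 (strain, nitrogen), 1494 (strain, carbon), 2532 (limitation, reference) and 1907 (limitation, deletion), and the highest other count was 0 in each, so that 1 split, the real one, was as large. For the average, 1 of 100 splits gave as many as 1763 genes, the real one, with 976 as the highest other. That share of 0.01 is the smallest that these splits can give. It does not separate the strains from the actin ratio, which was higher on every reference array. For the interaction, 2 of 100 gave as many as 976, and the highest other, 1763, was the split that swaps the strain labels within 1 limitation, which is the average strain effect and so a structure of the samples.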

How the results depend on the processing

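The tests with the actin ratio as a term, without reference carbon-limited arrays 2 and 3, and without reference nitrogen-limited arrays 2 and 3 were chosen only after the data had been seen. Unless stated, the cause of a change was not tested. With 3 arrays per group their number limits the precision, and 23.96% to 29.81% of probe sets per array lay below 12, where changes are not resolved. LEU3 gave no value at a mean intensity of at least 50, since that filter leaves it out.

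Leaving out 1 array at a time gave 793 to 1084 genes for the strain effect under nitrogen limitation, 1004 to 1852 under carbon limitation, 653 to 1411 for the interaction, 1414 to 2101 for the average, and 2148 to 2716 and 1436 to 1768 for the limitation effect in reference and deletion strain. FMP27 under nitrogen limitation ranged from -0.790 to -0.565 and did not pass without deletion array 1 (-0.616), deletion array 2 (-0.565) or reference array 1 (-0.571). Of the values of named genes with 1 array left out, the call was lost in 97 of 552 under carbon limitation, 59 of 558 under nitrogen limitation and 93 of 984 for the interaction.

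Requiring a 2-fold change by construction lowered the counts to 258 (nitrogen), 274 (carbon), 443 (interaction), 119 (average), 772 and 603 (limitation in reference and deletion), and dropped FMP27 (-0.657 and -0.84) and HMG2 under carbon limitation (-0.954). A fit of only the groups compared gave 805 genes under carbon limitation. After centring FMP27 did not pass under nitrogen limitation (-0.515), and as the mean of its probe sets it was 0.009 and -0.016. After quantile normalization GDH1 in the limitation effect of the reference changed sign (0.039).

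With the actin ratio as a term the counts were 54 under carbon limitation, 417 for the interaction, 220 for the average and 1289 for the limitation effect in the reference. FMP27 did not pass (-0.512 under nitrogen, -0.376 under carbon limitation), nor HMG2 under carbon limitation (-0.26). Under carbon limitation some genes changed sign, but none of them passed with the term, so an opposite effect is not shown. They were FUS3 (-0.125), NOP1 (-0.697), RIP1 (-0.197), LPD1 (0.086), NDT80 (0.287), MET28 (-0.158), TDH1 (0.203), SUL2 (-0.133), PGM2 (0.006), YOR302W (-0.058), SFG1 (-0.032), RPL7B (-0.298), RPA135 (-0.35) and GPH1 (0.527). The sign also changed for the average of NOP1 (-0.25), RIP1 (-0.13), NSR1 (-0.281), NDT80 (0.152), ASG7 (0.062), RPL7B (-0.151) and RPA135 (-0.16), and for DBP3 (-0.116) and RPA190 (-0.177) in the limitation effect of the reference.

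Without reference carbon-limited arrays 2 and 3 the counts were 338 (carbon), 634 (interaction), 1095 (average) and 1556 (limitation, reference), and the correlation of the strain effects was 0.192. HMG2 stood at -0.521 and FMP27 at -0.499, and the values of NOP1 (-0.054), GPH1 (0.039), DBP3 (-0.055) and RPA190 (-0.128) changed sign. Without reference nitrogen-limited arrays 2 and 3 the counts were 715 (nitrogen), 504 (interaction) and 1513 (limitation, reference), and FMP27 was -0.828 without passing.

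With an estimated correlation 1 list passed under nitrogen limitation, 1 under carbon limitation, 0 for the interaction, 0 for the average, and 6 and 5 for the limitation effect in reference and deletion. For the average, fry called 21 lists, quantile normalization 7 and the actin term 4. Under carbon limitation quantile normalization left 4, and without reference nitrogen-limited arrays 2 and 3 there were 9 under nitrogen limitation. Lists that reversed, with adjusted p, were classical Leu3 targets under nitrogen limitation by fry (0.00257), hexose transporters in the deletion strain by fry (1.84e-06), and ribosomal proteins in the limitation effect of the reference after quantile normalization (0.299). With the actin term they were sulfate (0.042), purine (0.917), beta-oxidation (0.0432), ribosome biogenesis (0.0148) and stress (0.789) under carbon limitation, and ribosome biogenesis in the average (0.482).

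Of 543 values of named genes, 355 kept direction and side of the threshold with the actin term and 165 lost the call, against 484 and 57 after quantile normalization, 490 and 47 after centring, and 536 and 5 with a variance trend. Of 150 list results, 94 were kept with an estimated correlation and 126 after quantile normalization.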

Other observations

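The tests in this part were planned, but 3 genes lay outside the rule for naming genes and were chosen after their values were seen. GAD1, glutamate decarboxylase, was lower in the deletion strain under nitrogen (-1.92) and carbon limitation (-1.12), with an average of -1.52 ± 0.19 (limma adjusted p = 5.56e-05). The subunit genes of type 1 phosphatase GIP2 and GIP3 fell on average by 1.51 ± 0.16 and 1.51 ± 0.15.

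Fits with the replicate number as a block gave 1043, 1358, 857, 1617, 2421 and 1787 genes for the 6 contrasts, and in 18 pairs of arrays with the same number the correlation of residuals ranged from -0.312 to 0.156.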
